A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

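RNA from 4 yeast samples was compared, 2 wild type and 2 labelled as WPL1 deletions, all grown in rich medium with glucose and harvested in exponential growth, per the labels' protocols. Total RNA was converted to double-stranded cDNA, fragmented, end-labelled with biotin and hybridised, per the labels' protocols. Labelling of double-stranded cDNA does not keep the strand, so signal from a gene and its antisense partner cannot be told apart. The deposited values are log2 expression values for each probe set, made by the authors with RMA from the affy package, per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays equal by quantile normalization and summarises the probes of a set. Versions are not given in the sources used here. The log2 scale was checked from the range of the values, which ran from about 2 to 15 in every array. Quantile normalization can hide a change in the total amount of RNA, so all differences are relative to the other transcripts.

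Of the 10928 probe sets, 7244 had 1 gene symbol in the platform annotation, 1 had several and 3683 had none. Gene IDs placed 5498 probe sets on S. cerevisiae genes in NCBI's gene table of assembly R64, and 12 symbols were updated through it. Probe sets of the same gene were averaged, which concerned 47 genes and left 5449 genes. The other 1746 named probe sets belong to S. pombe, and their 95th percentile in each array was taken as the limit of background. Chromosomes and neighbours of genes came from the systematic names. No genome was used, and no coordinates are given.

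Groups and replicate numbers came from the sample titles. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on all 4 arrays without covariates, which leaves 2 residual degrees of freedom. Gene lists and the 16 chromosomes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists or over the chromosomes. Camera with an estimated correlation and fry were run beside it. Lists needed at least 3 measured members. Of 38 lists fixed before the data were examined, the list of Ty retrotransposon genes had 0 members that could be named from the annotation used here and was not tested. The rule for named genes was also fixed then: RAD61 and its neighbours, the 10 genes per direction with the largest change among those past the threshold and of the same sign in both replicates, filled up by smallest unadjusted p where fewer passed, up to 4 members of each list past the threshold and up to 2 of each other list. A named gene that was not above background in any array of 1 group got a bound, with each array of that group set to the 95th percentile of its S. pombe probe sets, or to the gene's own value where higher. No fold is given where the bound was under 1, where the other group was above background in 1 of its 2 arrays alone, or where neither group was above background, which held for 7 named genes. Medians of lists include such genes at their measured values.

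The descriptions in the labels give arrays of the same replicate number a shared date tag, so the numbers pair the arrays. Deviations from the group means correlated between same-numbered arrays with r = 0.747 across genes. Correlations between arrays were 0.992 and 0.982 within replicates 1 and 2, against 0.944 between the wild type arrays and 0.953 between the deletion arrays. The SD over genes of the genotype difference was 0.21 in replicate 1 and 0.31 in replicate 2, and that of the difference between replicates was 0.54 in wild type and 0.50 in the deletion. The fit with the replicate number as a block leaves 1 residual degree of freedom. SEs of genotype differences are from the fit without the block unless stated, so they hold the difference between replicate numbers. No pair of arrays of a group was identical, with 39 and 25 of the 10928 probe sets at equal values.

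Chromosome shifts were measured in each replicate as the median difference of the genes of a chromosome minus that of all other genes. They were set against 10000 random lists of the same size drawn from 20 bins of mean expression, and intervals came from 10000 bootstrap draws of genes, which cover the spread between genes alone. The steps were tested on simulated data, 20 data sets of 5449 genes with 200 changed genes each. Alternatives were the replicate block, a filter on dim genes, all probe sets in the fit, the brightest probe set per gene, centring or quantile normalization over the S. cerevisiae genes, a trended and robust variance prior, a required fold of 1.5, and leaving out each array in turn. Fits without chromosome IX genes were added after the shift of that chromosome had been seen. Probe sets outside the S. cerevisiae genes entered no gene test apart from the fit of all probe sets.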

Results

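Total RNA from exponentially growing budding yeast was measured on 4 Affymetrix Yeast Genome 2.0 arrays, 2 from wild type cells (strain K699, mating type a) and 2 from cells labelled as carrying a deletion of WPL1. Wpl1, the yeast relative of Wapl, is a cohesin-associated protein that promotes release of the cohesin ring from chromosomes. Its gene appears under the standard name RAD61 (YDR014W). The comparison asks how the transcript levels of cells without Wpl1 differ from those of wild type. Median log2 values over the S. cerevisiae genes were 8.38 and 8.34 in wild type replicates 1 and 2 and 8.43 and 8.25 in deletion replicates 1 and 2. The array also carries 1746 probe sets for the fission yeast S. pombe, which served as background. Their medians were 4.52, 4.49, 4.42 and 4.56 in the same order, and 93.1% to 95.9% of the 5449 S. cerevisiae genes lay above the 95th percentile of these probe sets. The labels do not say that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, and their number limits the precision.

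RAD61 was at background in both deletion arrays. Its log2 value was 6.49 ± 0.080 (SD, n = 2) in wild type and 4.20 ± 0.34 (SD, n = 2) in the deletion. Wild type values of 6.43 and 6.55 lay at the 98.5th and 98.6th percentile of the S. pombe probe sets. Deletion values of 3.96 and 4.44 lay at the 26.6th and 43.4th percentile. The measured values differed by -2.29 on the log2 scale (SE 0.27), but with the deletion at background only a bound can be read. With the deletion arrays set to the 95th percentile of the S. pombe probe sets, RAD61 was at least 1.46-fold lower in the deletion. Its adjusted p was 1 in limma and 0.141 in limma with the replicate block, so the difference missed the threshold in both fits. Of the measured neighbours, DAD1, a kinetochore subunit, had a log2 difference of 0.04 (SE 0.23) and SNQ2, a drug exporter, 0.05 (SE 0.24). PSF1, a subunit of the GINS replication complex, had -0.22 (SE 0.26). KCS1, an inositol phosphate kinase, had -0.35 (SE 0.27) and RPL4B, a ribosomal protein, 0.37 (SE 0.37). These SEs are from the fit without the block and hold the difference between replicates. RPL4B was at 0.38 in replicate 1 and 0.36 in replicate 2, and its SE with the block was 0.14. None of these 5 neighbours passed in either fit.

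**Figure D1:**
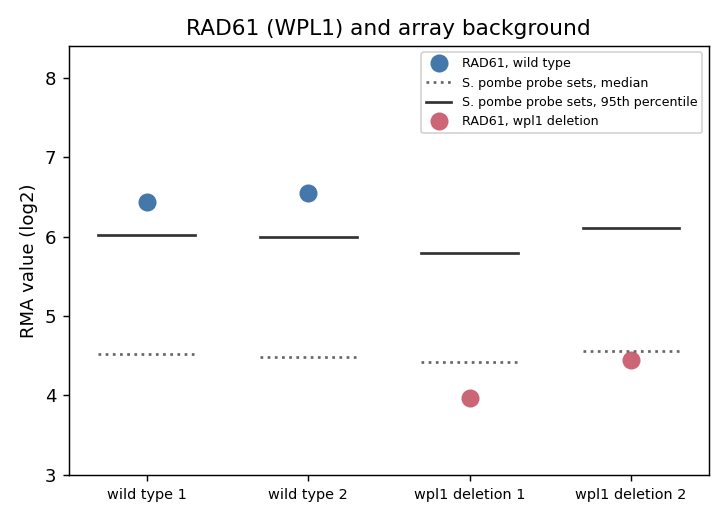
RMA values (log2) of RAD61 in each of the 4 arrays (points), with the median (dotted lines) and the 95th percentile (solid lines) of the S. pombe probe sets in the same array. Wild type values of 6.43 and 6.55 lie above the 95th percentile of their arrays, and deletion values of 3.96 and 4.44 lie below the median of theirs.

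Across the genome, 0 genes were higher and 0 lower in the deletion at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 5 higher and 5 lower genes, against 272 in either direction by chance among 5449 genes. With the replicate number as a block, 0 genes passed in either direction, and 83 were higher and 73 lower at an unadjusted p under 0.05. The smallest adjusted p was 1 without the block and 0.141, that of RAD61, with it. In simulated data with a spread estimated from the block fit, limma without the block recovered 0% of genes changed 1.5-fold, 2-fold or 4-fold. Its error held the difference between replicate numbers. With the block, limma recovered 8.51%, 72.4% and 99.2%, with 251 false calls in 20 data sets. Each data set held 200 changed genes, which loosens the adjusted threshold. In the measured arrays RAD61 missed that threshold even with the block. These rates therefore do not carry over to data with few changes, and the count of 0 with the block does not exclude changes of these sizes. With 0% recovered, the count of 0 without the block says nothing about the absence of changes.

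The genes with the smallest p among those that moved the same way in both replicates are given as values that did not pass. Among the higher ones, the small heat shock protein HSP12 had a log2 difference of 0.84 (SE 0.32). HSP26, another small heat shock protein, was not above background in wild type and was at least 1.28-fold higher in the deletion. PIR3, a cell wall protein, had 0.73 (SE 0.30, and 0.14 with the block). The other 7 of the 10 named rises lie on chromosome IX. DCG1 was not above background in wild type and was at least 1.53-fold higher in the deletion. Its log2 values were 5.67 and 5.80 in wild type replicates 1 and 2 and 6.50 and 6.74 in deletion replicates 1 and 2. Its measured rise was thus not confined to replicate 2. HYR1, a peroxidase, was at 0.86 (SE 0.35), and MET28, a regulator of sulfur metabolism above background in 1 of 2 wild type arrays, at 0.85 (SE 0.35), with COA1 at 0.78, GTT1, a glutathione transferase, at 0.75, SEC24, a COPII coat subunit, at 0.74, and ARC15, an Arp2/3 subunit, at 0.72. Chromosome IX as a whole stood apart in deletion replicate 2, as described below for the chromosomes. Of the lower genes other than RAD61, YGR035C had -0.74 (SE 0.28), YJL047C-A -0.67 (SE 0.24) and PRP24, a splicing factor, -0.59 (SE 0.24). YKR075C had -0.56 and PRM1, a membrane protein of mating, -0.49. SPO23, SRT1, YGL081W and SRL4 were not above background in any array, so no difference is given for them.

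**Figure D2:**
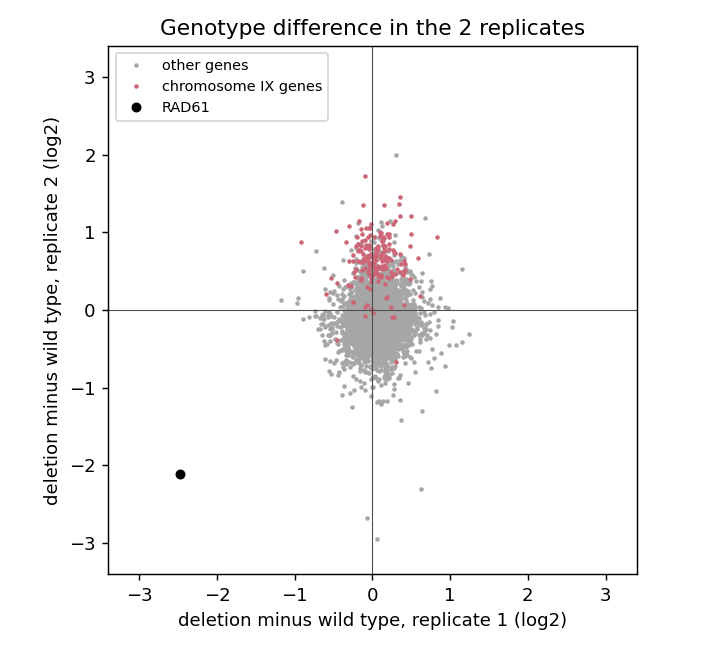
Log2 difference between deletion and wild type in replicate 1 (horizontal axis) and in replicate 2 (vertical axis) for each of the 5449 genes, with chromosome IX genes in red and RAD61 in black. RAD61 is low in both replicates, chromosome IX genes as a set are raised in replicate 2 alone, and r across the other 5257 genes is 0.012.

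Of the 37 gene lists tested, 8 passed limma's camera test with its preset correlation, 4 higher and 4 lower in the deletion. All 8 calls ended with an estimated correlation, where each list had adjusted p = 0.995, and fry called 0 lists, with a smallest adjusted p of 0.987. Neither test called the shift of chromosome IX described below, for which fry gave adjusted p = 0.955. With an estimated correlation, doubling that chromosome in 1 simulated array gave a call in 0 of 20 data sets. Both checks concern a shift in 1 array, so neither shows how these tests treat a shift present in both deletion arrays. The loss of the 8 calls therefore does not decide whether the lists moved in both. Camera with the preset correlation called the simulated shift of 1 array in 20 of 20 data sets. Its 8 calls therefore do not show a shift in both deletion arrays either. No member of any list passed limma's test over all genes, and 0 passed when adjusted over the list alone. That fit recovered 0% of simulated genes changed 4-fold when adjusted over all genes, so its count over all genes does not weigh against the calls. Recovery with adjustment over a list alone was not simulated. With the replicate block, 0 members of any list passed over the list alone. Over all genes, the block fit recovered 8.51% of simulated genes changed 1.5-fold and 99.2% of those changed 4-fold, with 200 changed genes per data set. Each of the 8 calls also ended or turned when 1 of the arrays was left out. Such a fit mixes the genotype with the date. The leave-out results here and for the lower lists can therefore come from the difference between dates. The counts of members above 0 are to be read against all genes, whose median log2 difference was -0.025, so most genes lay below 0. Mitochondrial ribosomal proteins were called higher, with a median log2 difference of 0.16 over 66 genes, 62 of them above 0 (camera adjusted p = 3.58e-11). Without wild type replicate 2 this call ended and the median was 0.06. RSM25 had 0.54 (SE 0.34), RSM23 0.38 (SE 0.23), MRPL11 0.36 (SE 0.26) and RSM10 0.33 (SE 0.24). RSM25 lies on chromosome IX and was at -0.03 in replicate 1 and 1.11 in replicate 2. Proteasome and protein folding genes had a median of 0.13 over 41 genes, 38 of them above 0 (camera adjusted p = 9.71e-06), and its median ran from -0.11 to 0.45 with arrays left out. The Hsp70 chaperones SSA2 and SSA1 had 0.58 (SE 0.46) and 0.53 (SE 0.49), with SEs of 0.19 and 0.23 with the block. HSP10, a mitochondrial chaperonin, had 0.36 (SE 0.28, and 0.15 with the block). RPN2, a proteasome subunit on chromosome IX, had 0.45 (SE 0.29), with 0.07 in replicate 1 and 0.82 in replicate 2. The general stress response list had a median of 0.17 over 32 genes, 29 of them above 0 (camera adjusted p = 5.13e-05), and its median ran from -0.25 to 0.71 with arrays left out. HSP26 and HSP12 led it. HSP104, a disaggregase, had 0.48 (SE 0.52, and 0.21 with the block) and TSL1, of trehalose synthesis, 0.44 (SE 0.46, and 0.16 with the block). Respiratory chain and ATP synthase genes had a median of 0.12 over 35 genes, 30 of them above 0 (camera adjusted p = 0.000551). This call ended without deletion replicate 2, where the median was 0.05, and without wild type replicate 1, where it was 0.13. CYC1, cytochrome c, had 0.40 (SE 0.24), ATP15 0.27 (SE 0.23), CYT1 0.24 (SE 0.24) and ATP16 0.21 (SE 0.26).

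The M/G1 transcripts were called lower, with a median log2 difference of -0.18 and 5 of 27 genes above 0 (camera adjusted p = 0.00105). With 1 array left out the median ran from -0.38 to 0.043, and the direction turned without wild type replicate 2. PCL9, a cyclin, had -0.57 (SE 0.30), DSE4, a daughter cell glucanase, -0.52 (SE 0.29), PIR1, a cell wall protein, -0.47 (SE 0.26) and RME1, a repressor of meiosis, -0.32 (SE 0.27). Amino acid biosynthesis genes under Gcn4 had a median of -0.14 with 7 of 44 genes above 0 (camera adjusted p = 0.00269), and the direction of the test turned without wild type replicate 2 (median -0.07, adjusted p = 0.417). LYS9 had -0.54 (SE 0.35), ARO4 -0.40 (SE 0.31), LEU1 -0.39 (SE 0.32) and HIS1 -0.35 (SE 0.26). Ribosome biogenesis genes had a median of -0.12 with 12 of 57 genes above 0 (camera adjusted p = 0.0316). This call ended with all probe sets in the fit (adjusted p = 0.0703), with arrays centred on the gene median (0.0576) and without the chromosome IX genes (0.0591). With arrays left out the median ran from -0.32 to 0.087. RIO1 had -0.30 (SE 0.24), RRB1 -0.28 (SE 0.25), UTP21 -0.25 (SE 0.29) and NOP58 -0.24 (SE 0.24). Seripauperin and other subtelomeric families had a median of -0.07 with 9 of 33 genes above 0 (camera adjusted p = 0.0284). The call ended without deletion replicate 1, where the median was -0.13, and without wild type replicate 1, where it was -0.16. PAU5 had -0.43 (SE 0.25), PAU23 -0.39 (SE 0.26), COS8 -0.37 (SE 0.24) and PAU17 -0.35 (SE 0.24). With its brightest probe set alone PAU23 had -0.64. Glycolysis genes, with a median of 0.11 over 17 genes, did not pass camera (adjusted p = 0.126). They passed with the replicate block (0.0372) and without the chromosome IX genes (0.0467), and did not with the block and an estimated correlation (adjusted p = 0.99).

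The shifts of these 8 lists differed between replicates. Relative to all genes, mitochondrial ribosomal proteins were at 0.03 in replicate 1 and 0.38 in replicate 2, the stress list at 0.06 and 0.35, and proteasome and folding genes at 0.03 and 0.30. Respiratory genes were at 0.07 and 0.18. M/G1 transcripts were at 0.03 and -0.33, Gcn4 targets at 0.09 and -0.30, and ribosome biogenesis genes at 0.04 and -0.20, so these 3 lists had opposite signs in the 2 replicates. The subtelomeric families were at -0.12 and -0.05, the one list with the larger shift in replicate 1. Across the 5257 genes other than RAD61 and those of chromosome IX, the genotype differences of the 2 replicates had Pearson r = 0.012 and Spearman rho = 0.015, and 50.4% shared a sign after centring. Genes are not independent replicates.

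The lists closest to the known role of Wpl1 did not pass. Cohesin and its regulators had a median log2 difference of -0.07 over 12 genes (camera adjusted p = 0.471), with HOS1, the Smc3 deacetylase, at -0.31 (SE 0.24) and ECO1, the Smc3 acetyltransferase, at -0.29 (SE 0.24). Condensin and condensation genes had a median of -0.03 over 12 genes (0.986), with BIR1 at 0.27 (SE 0.27) and SLI15 at -0.24 (SE 0.24). The Smc5-Smc6 complex had -0.12 over 8 genes (0.295), with SMC5 at -0.40 (SE 0.30) and NSE4 at -0.19 (SE 0.23). Genes of cohesion establishment had a median of -0.01 over 15 genes, with RFC5 at -0.31 and DCC1 at 0.18. Kinetochore and checkpoint genes had 0.01 over 31 genes, with MAD3 at -0.47 and MTW1 at -0.32. G1/S transcripts had -0.02 over 30 genes, with PCL1 and PRI1 both at 0.35. PCL1 was at 0.37 and 0.33 in replicates 1 and 2, and PRI1, on chromosome IX, at 0.01 and 0.69. The CLB2 cluster had -0.01 over 23 genes, with MOB1 at 0.34 and SPO12 at 0.18. MOB1 also lies on chromosome IX and was at 0.04 and 0.64 in replicates 1 and 2. For condensin, the kinetochore, the CLB2 cluster and G1/S, the test pointed up, with adjusted p from 0.675 to 0.986, while the median or mean was below 0 for each. Histone genes had 0.05 over 8 genes, with HHO1 at 0.23 and HHF1 at -0.12. DNA damage response genes had -0.06 over 20 genes, with HUG1 at -0.56 and PLM2 at -0.37. Silencing factors had -0.05 over 22 genes, with RIF2, above background in 1 of 2 deletion arrays, at -0.52 and SIR4 at -0.34.

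Other lists gave small medians and did not pass. Cytosolic ribosomal proteins had a median log2 difference of 0.01 over 128 genes, with RPS22B at 0.51 and RPS24B, on chromosome IX, at 0.35. Glucose-repressed genes had -0.06, with ADH2 at -0.43 and PCK1 not above background in wild type and above it in 1 of 2 deletion arrays. The galactose regulon had 0.04, with GAL7 and GAL1 not above background in wild type. Within glycolysis, TDH1 had 0.22 and GPM1 0.16. Sulfur amino acid genes had 0.04, with MET28 as given and CYS4 at -0.36. Purine genes had 0.02, with GCV3 at 0.50 and ADE17 at -0.47. The phosphate regulon had -0.11, with PHM8 at -0.27, and the iron regulon -0.08, with FRE5 at -0.49. PHM7 and FIT1 of these lists were not above background in wild type and each was above it in 1 of 2 deletion arrays, so no fold is given. Ergosterol genes had -0.03, with ERG11 at -0.26 and ERG24 at 0.24. Cell wall integrity genes had a median of -0.02 and a mean of 0.02, with PIR3 and PIR1 moving apart. Pheromone response genes had -0.06, with PRM5 at 0.58 and PRM1 at -0.49. PRM5 lies on chromosome IX and was at 0.18 in replicate 1 and 0.98 in replicate 2. Alpha-cell genes had -0.03, with HMLALPHA1 not above background and MF(ALPHA)2 at -0.19. Haploid-specific genes had -0.02, with RME1 as given and STE5 at -0.21. Meiosis genes had -0.06, with REC114 not above background and SPO20, above it in 1 of 2 deletion arrays, at -0.40. Strain marker genes had -0.14, with ADE2 at 0.29 and CAN1 at -0.17. The 5 neighbours of RAD61 had a median of 0.04 and a mean of -0.02. By position, 312 centromere-proximal genes had 0.00, with NTH2 at 0.60 and PDH1 at 0.51, 340 telomere-proximal genes -0.03, led by DCG1 and COA1, and 2798 genes in convergent pairs -0.03, with RAD61 and DCG1 as their smallest p. The smallest camera adjusted p of the lists in this paragraph other than glycolysis was 0.134, for the sulfur amino acid genes.

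Of the 16 chromosomes, chromosome IX alone passed camera with the preset correlation (adjusted p = 1.28e-56), and it did not with an estimated correlation (adjusted p = 0.98). Its 191 genes had a median log2 difference of 0.35, and this came from deletion replicate 2. Relative to the genes of the other chromosomes, the median of chromosome IX was 0.77 in replicate 2 (95% bootstrap interval over genes 0.73 to 0.80), a fold of 1.71, with 189 of 191 genes above the other chromosomes' median. In replicate 1 it was -0.002 (interval -0.03 to 0.03), with 94 of 191 genes above. The left arm had a median of 0.75 over 153 genes and the right arm 0.80 over 38 genes in replicate 2. In 9 blocks of neighbouring genes the medians ran from 0.69 to 0.90. The other 15 chromosomes lay between -0.04 and 0.03 in that replicate. Each replicate compares 1 deletion array with 1 wild type array, so these values have no replicate of their own. Simulated data with chromosome IX doubled in 1 array gave the camera call in 20 of 20 data sets with the preset correlation and in 0 of 20 with an estimated one.

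**Figure D3:**
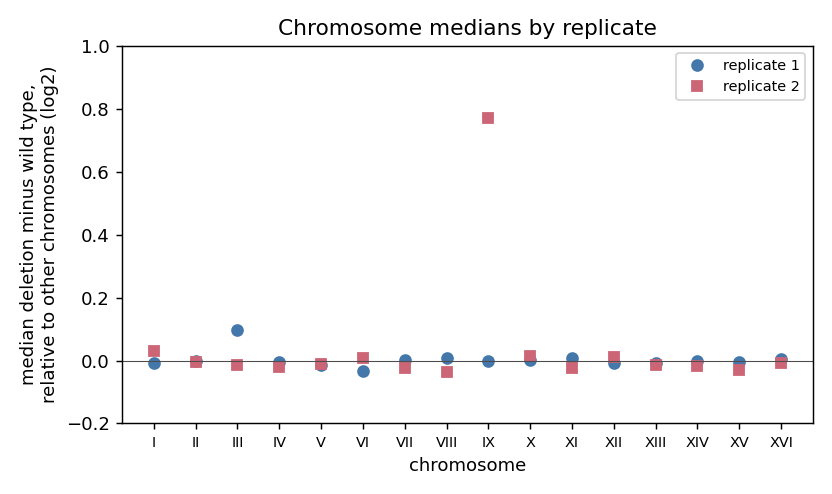
Median log2 difference between deletion and wild type for the genes of each of the 16 chromosomes, relative to the genes of all other chromosomes, in replicate 1 (circles) and replicate 2 (squares). Chromosome IX in replicate 2 lies at 0.77, and chromosome III in replicate 1 at 0.10.

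**Figure D4:**
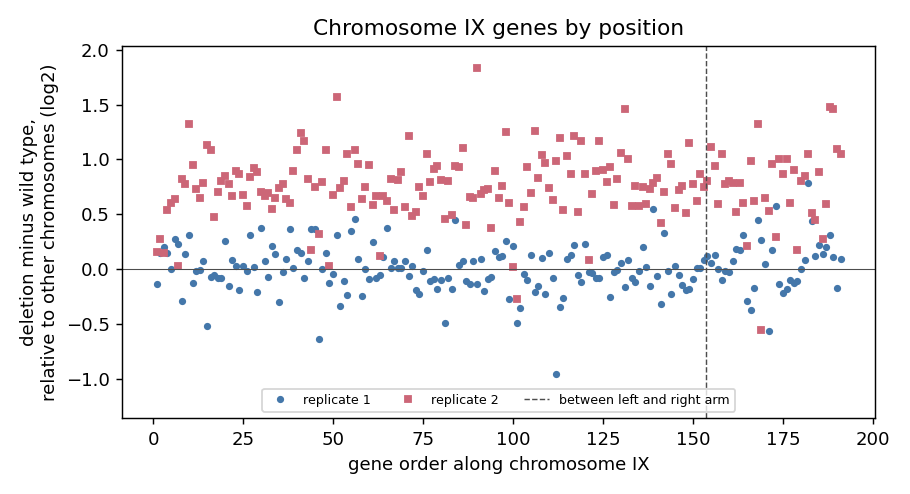
Log2 difference between deletion and wild type, relative to the median of the other chromosomes, for the 191 chromosome IX genes in their order along the chromosome, in replicate 1 (circles) and replicate 2 (squares), with the boundary of the arms as a dashed line. Replicate 2 values lie around 0.77 along both arms and replicate 1 values around 0.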

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

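Probe sets outside the S. cerevisiae genes showed a strong signal in each deletion array that wild type arrays lacked, and all tests in this part were chosen after that signal was seen. Among 5430 such probe sets, the one annotated as S. pombe his5, an enzyme gene of histidine synthesis, had a log2 value of 11.9 in deletion replicate 1 and 4.12, 3.68 and 3.70 in wild type replicates 1 and 2 and deletion replicate 2. With wild type set to the higher 95th percentile of its S. pombe probe sets, 6.02, it lay at least 5.89 above wild type. A reporter probe set without a gene symbol had 12.4 in deletion replicate 2 and 4.56, 4.04 and 3.66 in wild type replicates 1 and 2 and deletion replicate 1. That is at least 6.43 above wild type on the same basis. What this probe set detects is not known here, so whether deletion replicate 2 goes with its labelled marker is open. S. pombe his5 is in wide use as a selectable marker in yeast gene deletion cassettes, and the labels give both deletion samples a KAN marker.

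Tables argue against 3 explanations of this pair of signals. The next largest upward departure of a probe set in either deletion array was 2.06, too small for array noise as the source. S. pombe RNA in the sample would raise other S. pombe probe sets, and the median departure of the other 1745 in deletion replicate 1 was -0.10. A marker cassette shared by both deletion cultures that held the sequence of a probe set would light that probe set in both arrays. In the other deletion array neither exceeded 3.70. A shared cassette that neither probe set detects is not addressed by these values. A candidate explanation is that the deletion cultures carried different marker genes, with a lower level of 11.9 for the pair in the arrays where they were bright; as a hypothesis found on the same data it needs the sequence of the reporter probe set and the strain records.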

How the results depend on the processing

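Fits without chromosome IX genes and the relative median of chromosome IX with arrays left out were chosen after the data had been seen, and the other alternatives were planned. In every setting that kept all 4 arrays, 0 genes passed in either direction, RAD61 kept its direction, and 7 to 9 lists passed camera with the preset correlation. With an estimated correlation 0 lists and 0 chromosomes passed, and with fry 0 lists. RAD61 was removed by the filter on dim genes, which left 5195 genes. In the replicate block fit the paired arrays gave 0 genes higher and 0 lower, 9 lists and 1 chromosome, and RAD61 at -2.29 with adjusted p = 0.141 in limma (0.0846 without chromosome IX genes); glycolysis was its one changed list call. Leaving out 1 array leaves a lone array assumed to vary like the other group, and mixes the genotype with the date. Over these 4 settings the number of higher genes ran from 0 to 1 and of lower genes from 0 to 2. Without wild type replicate 1, ARG1, FRE7 and RAD61 passed, and without wild type replicate 2, RAD61. The RAD61 log2 difference ran from -2.53 to -2.05, with adjusted p from 0.00224 to 0.817 in limma. From 10 to 14 lists passed, and 0 to 1 chromosomes, 0 without wpl1 deletion replicate 2. The relative median of chromosome IX ran from 0.036 without that array to 0.77 without deletion replicate 1. The direction of camera's test turned with the array left out for 10 lists, whose medians ran from -0.16 to 0.13 for G1/S transcripts, -0.11 to 0.18 for the CLB2 cluster, -0.38 to 0.27 for the iron regulon, -0.38 to 0.043 for M/G1 transcripts, -0.25 to 0.71 for the stress list, -0.32 to 0.087 for ribosome biogenesis, -0.29 to -0.041 for Gcn4 targets, -0.11 to 0.45 for proteasome and folding genes, -0.094 to 0.032 for convergent pairs and -0.20 to 0.13 for the pheromone response. Beyond this mixing of date and genotype the cause was not tested, nor was it for the loss of calls with an estimated correlation or fry. Signal over background limits RAD61 and other dim genes to bounds.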

Other observations

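The larger difference in these arrays lay between the 2 replicate numbers, which carry different dates. All tests in this part were chosen after the results were seen, except the correlation with the date difference. In a limma fit with genotype and replicate, 335 genes were higher and 721 lower in replicate 2 at an adjusted p under 0.05, with a median log2 difference of -0.13 over all genes. Without chromosome IX genes in the fit, 1302 genes passed in either direction, against 1056 with them. HSP42, a small heat shock protein, was 7.58-fold lower in replicate 2 (log2 -2.92, SE 0.22, adjusted p 0.0234), and HSP30, a stress-induced membrane protein, 6.97-fold lower (log2 -2.80, SE 0.18). GLK1, glucokinase, was 4.17-fold lower (log2 -2.06, SE 0.14), TPS2, of trehalose synthesis, 3.28-fold lower, and PHO11, an acid phosphatase, 4.73-fold lower. CLB1, a mitotic cyclin, was 2.87-fold higher (log2 1.52, SE 0.14).

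Of the general stress response list, 21 of 32 genes fell and 0 rose in replicate 2 (median log2 -0.93, camera adjusted p = 4.64e-07). In the iron regulon 14 of 26 fell and 0 rose (median -0.61, camera adjusted p = 5.49e-05), and of the proteasome and folding genes 15 of 41 fell and 0 rose (median -0.45, camera adjusted p = 0.00193). Ribosome biogenesis was called higher, with 10 genes up and 1 down of 57, as were the CLB2 cluster, with 6 up and 0 down of 23, and the pheromone response, with 6 up and 1 down of 26. In all, 16 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.818 for each of these 6). Date, culture and array lot cannot be told apart here. A strain difference between the 2 deletion samples would not move wild type. The differences between replicates correlated between the genotypes with r = 0.747 across genes, which argues against such a strain difference as the source of the shared part. For the part seen in the deletion alone, it cannot be told apart from the others. The deletion arrays also differed in 2 probe sets outside the S. cerevisiae genes. Relative to other chromosomes, chromosome IX genes shifted by 0.72 from deletion replicate 1 to 2 and by -0.01 between the wild type replicates.

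Chromosome IX genes were raised in deletion replicate 2. The tables argue against an effect of the deletion present in both deletion cultures, since the relative median in replicate 1 was -0.0017. They argue against intensity-dependent normalization, where the highest of 10000 matched random lists reached 0.079, and against an array defect, where the highest of the other 15 chromosomes was 0.030. A gain of part of the chromosome would leave some block near 0, and the lowest block was at 0.69. A gain of the whole chromosome in that culture is a candidate explanation, with medians of 0.64, 0.81 and 0.86 in the lowest, middle and highest of 3 equal groups of its genes by expression, each under the 1 of a doubled copy number; no DNA was analysed here, so it stays a hypothesis.

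The list shifts, other than that of the subtelomeric families, were larger in replicate 2. List members on chromosome IX do not account for them, since 4 of the 8 lists had 0 members there and the other 4, with 1 to 3, still passed without the genes of that chromosome, although without them ribosome biogenesis, which has 0 members there, lost its call (adjusted p = 0.0591) and glycolysis gained one (adjusted p = 0.0467). Whether an effect of the deletion was present in both cultures was judged by a yardstick rewritten 2 times after the values were seen: the first asked for a replicate 1 shift of at least 50% of the replicate 2 shift with the same sign, which 1 of the 8 lists had, and argued against such an effect, and the last set the difference between replicates against the 29 lists not called, whose largest value of 0.40 was exceeded by 0 of the 8 and whose 95th percentile of 0.25 by 5 of the 8. It is left open because 1 pair of arrays per replicate gives no spread between cultures, which is also missing from the 95% intervals over genes of the difference between replicates that excluded 0 in 6 of the 8. A growth-state difference along the date axis was not put to a usable test, since the r of -0.215 across 5257 genes was taken between the replicate 2 genotype difference and a date difference that holds the same arrays, and it decides nothing.

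In replicate 1, chromosome III had a relative median of 0.10, with 100 of 148 genes above the other chromosomes' median, above the highest of 10000 matched random lists at 0.07. In replicate 2 it was at -0.01. YCL021W-A had log2 values of 9.32, 9.25 and 9.38 in wild type replicates 1 and 2 and deletion replicate 1 and 6.31 in deletion replicate 2. YLR154C-H had 13.9, 13.9, 13.8 and 11.2 in the same order, and ARG1 had 10.5 in wild type replicate 2 against 8.28, 8.90 and 8.22 in wild type replicate 1 and deletion replicates 1 and 2.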
